A study of Mus musculus with 4 samples.

How the data were processed

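Single cells were obtained from the corpus callosum of male C57BL/6 mice aged 13 weeks, per the labels. The cells were stained for CD11b, a surface integrin of myeloid cells, and live nucleated single cells positive for it were sorted by flow cytometry. Libraries were made with a droplet-based kit that reads the 3′ end of transcripts and marks each molecule with a unique molecular identifier (UMI). Of 4 libraries, 2 came from untreated animals (week 0) and 2 from animals given cuprizone (week 5), a copper chelator that causes loss of oligodendrocytes and myelin. The labels do not say that the libraries are separate animals, so p-values measure the spread between these samples, which may be technical.

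The authors deposited whole-number UMI counts per gene and cell barcode, not normalized, as the values themselves show. STAR, Cell Ranger 3.0.0, Seurat 4 and the mouse build mm10 are named in the submitters' processing notes, with no role given for each. Each deposited count table held 1000 barcodes, the lowest total being 510 UMIs, and its own list of 13920 to 15256 genes; how cells and genes were chosen is not given in the sources used here. The highest number of genes in a cell differed between the tables (2999 and 6615 for week 0 replicates 1 and 2, 3999 and 2996 for week 5 replicates 1 and 2). Of 16342 genes in any table, 12904 were in all of them. A gene that a table did not list was taken as 0 there; such genes held at most 0.362% of a table's UMIs.

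Cells with at least 500 genes and at most 10% mitochondrial UMIs were used, which removed 272 of 4000 barcodes, and scrublet (in scanpy 1.11.5) marked 24 of the remaining 3728 as doublets (0.644%). The other 3704 cells were scaled to 10000 UMIs, log-transformed, reduced to 30 principal components of 2000 variable genes, joined to 15 neighbours and clustered (Leiden) at resolution 1 into 12 clusters. Clusters were named from markers fixed before the data were examined. The rule that turned markers into names was set after the clusters were seen. Of the classes other than microglia, the one with the highest summed markers gave its name if it had the most markers among the 10 leading genes. It needed at least 2 there and at least 3 detected. A cluster was microglia-like if no other class had 2 leading markers, or more of them than microglia. Its summed microglia markers also had to be at least 10 times those of any other class. Clusters far below the median depth of their libraries, with no leading microglia marker, and all others stayed unnamed. It gave 8 microglia-like clusters with 3561 cells, 1 border-associated macrophage-like cluster with 75 cells, and 3 unnamed clusters of 22, 31 and 15 cells.

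The ranking of leading genes was also settled after the data were seen, and 1 decision rests on it. The microglia-like cluster led by Apoc1, Fabp5, Cst7, Apoc4 and Spp1, in this order, is called the Spp1-led cluster below. Spp1 was also among the 10 leading genes of the Ccl4-led cluster, so it does not mark the Spp1-led cluster alone. For the Spp1-led cluster, 5 rankings were looked at. In 2 of them the monocyte marker Fn1 stood among the 10 leading genes with 0 microglia markers, which by the rule for comparing a class between groups would have barred the comparison of microglia-like cells between groups. In the other 3 it did not, and 1 of these was kept. The comparison was therefore also run without this cluster, and a comparison of all cells together, which needs no names, stands beside it.

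The UMI counts of each library were summed over the microglia-like cells and, separately, over all cells. The sums were compared between week 5 and week 0 with edgeR 4.0.16 (R 4.3.3), using its quasi-likelihood test with TMM factors, its own filter on low counts and the Benjamini-Hochberg adjustment; genes with an adjusted p under 0.05 are called changed. Levels (CPM, counts scaled to the effective library size) are given as mean ± SD over the 2 libraries of a group; sums of markers and the values of macrophage-like cells are relative to the total UMIs of the cells concerned. The test was tried on 10 simulated data sets drawn from the means and library sizes of the microglia-like sums (10883 to 10918 genes). In each, 200 genes were changed, all with a mean log2 CPM of at least 5. The test recovered 56.8% of 2-fold and 99.9% of 4-fold changes, and every recovered change had the right sign. Recovery of genes at lower levels was not measured. On average 7.94% of the calls were false (3.8% to 11.5%), above the nominal level. A fold against 0 UMIs is a lower bound, taken for each week 5 library against a floor of 3 UMIs over the week 0 group, and a gene with 1 to 3 UMIs at week 0 has its ratio of counts summed over both libraries of each week, with a 95% counting interval. The upper limit that a count of 0 allows is likewise 3 counts of the total of cells or UMIs. Intervals and floors cover counting error only.

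The 20 gene lists were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, and again with an estimated correlation. Shares of cells have exact (Clopper-Pearson) 95% intervals and an exact two-sided permutation test, whose smallest possible p for 2 against 2 libraries is 0.333. Shares of cells with a UMI were taken after each cell was thinned to 1000 UMIs; 145, 69, 60 and 101 shallower microglia-like cells of week 0 replicates 1 and 2 and week 5 replicates 1 and 2 were left out. Spearman's rank correlation between list scores was computed over microglia-like cells within each library, without a p-value. Genes are named by a rule fixed before the data were examined: 16 fixed genes, the 8 largest rises and 8 largest falls among called genes with a mean log2 CPM of at least 5 and both groups apart, and up to 4 members per list with the smallest p (or, where no member passed, 2 with the highest level). Positions of the 73 named genes were taken by symbol from the GENCODE annotation of GRCm38, the build also called mm10 (mouse release 21). The result of 1 named gene is not reported here.

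The planned tests within macrophage-like cells, and of whether a change differed between them and microglia-like cells, were not run because fewer than 20 such cells remained in each week 0 library. The counts of replicates differed by more than sampling noise, with a chi-square per degree of freedom of 14.0 between the week 0 and 29.2 between the week 5 libraries, so neither pair is 1 library deposited again; this does not tell technical from biological spread. Alternatives planned before the data were examined covered normalization (size factors, library size only), the test (DESeq2 1.42.0, limma-voom, camera and fry for lists), the gene filter, the cell filter, doublets, thinning, clustering resolution, a fold of at least 2, the replicate number as a block, and each library left out in turn. Alternatives chosen after seeing the data were a common limit of 2996 genes per cell, no AY036118 clusters (both with AY036118 among their 10 leading genes), no Spp1-led cluster, no Cxcl10-led cluster (for the interferon genes), only genes listed in every table, and crossed replicate numbers. Results with replicate numbers in the fit are given only with the dependence on the processing.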

Results

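Gene expression was measured in single CD11b-positive cells of the mouse corpus callosum before (week 0, 2 libraries) and after cuprizone treatment (week 5, 2 libraries). The count tables held 2415001 and 4631622 UMIs for week 0 replicates 1 and 2, and 6559032 and 3322818 for week 5 replicates 1 and 2, over 1000 barcodes each. The median cell had 1454, 3764.5, 6028.5 and 1924 UMIs in the same order. The series names microglia and macrophages as the sorted cells, and the comparison asks how their transcripts differ between demyelinated and untreated tissue.

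Most cells were microglia-like at both times: 97.4% and 99.2% of the cells of week 0 replicates 1 and 2, and 94.7% and 93.3% of those of week 5 replicates 1 and 2. With no cell filter the shares were 68.6% and 81.9% against 87.9% and 80.6%, so that the order of the means turned. But fewer cells were then named microglia-like (683, 801, 861 and 803 against 901, 902, 905 and 853, in the same library order). Unnamed cells went from 8, 2, 22 and 36 to 293, 168, 86 and 143. Cells named microglia-like with the filter were thus left unnamed without it, and these shares do not compare composition alone. Border-associated macrophage-like cells, led by Mrc1, Pf4 and MHC class II genes, made up 1.73% (16 of 925; interval 0.992% to 2.79%) and 0.550% (5 of 909; 0.179% to 1.28%) at week 0. They made up 3.03% (29 of 956; 2.04% to 4.33%) and 2.74% (25 of 914; 1.78% to 4.01%) at week 5. Both week 5 shares lay above both week 0 shares, but the exact permutation test could not pass a threshold (two-sided p = 0.333, the smallest it allows, n = 2 and 2). The CD11b gate sets which cells are seen. Cells of the unnamed clusters, led by Ttr, by S100a6 and Ccl5, or by Pex5l, made up 0.865%, 0.220%, 2.30% and 3.94% of the 4 libraries in the same order.

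In microglia-like cells, genes known from microglia near damaged or degenerating tissue were far higher at week 5. Spp1, which encodes the secreted glycoprotein osteopontin, went from 1.24 ± 0.00423 to 949 ± 716 CPM (SD, n = 2 each; log2 fold change 9.54, SE 0.73, edgeR adjusted p = 5.03e-05). Apoe, the main lipid carrier of the brain, went from 574 ± 320 to 40050 ± 25080 CPM (log2 fold change 6.13, SE 0.84, adjusted p = 0.00150). The receptor tyrosine kinase Axl rose by a log2 fold change of 6.14 (SE 0.52), the galectin Lgals3 by 6.05 (SE 0.38) and the lipoprotein lipase Lpl by 5.04 (SE 0.53). At week 0 only 3 of 901 and 4 of 902 microglia-like cells had a UMI of Spp1, and 6 and 10 had one of Axl. The small week 0 SD of Spp1 thus rests on few counts and does not show precision. In all, 378 of 11061 tested genes changed, 340 upward and 38 downward. Falls were smaller: the largest among the named genes were those of Klhdc8b, by 1.46 on the log2 scale (SE 0.26), and Camk2n1, an inhibitor of a calcium-dependent kinase, whose log2 fold change was -1.43 (SE 0.23). With the library size as the only scaling, 315 genes rose and 108 fell (74.5% upward against 89.9%), and the median log2 fold change of all genes moved to -0.25. The count was 835 with no gene filter, 580 with a common limit on genes per cell and 137 with each cell thinned to 1000 UMIs.

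The largest rises also took in genes that were nearly silent at week 0. The apolipoprotein gene Apoc4 and the glycoprotein gene Gpnmb, both without a UMI at week 0, were at least 486-fold and at least 328-fold higher in week 5 replicate 1, and at least 81.8-fold and at least 46.4-fold in replicate 2. Apoc1 had 1 UMI at week 0 against 4198 at week 5, a ratio of 3743 (counting interval 671 to 147887), and the fibronectin gene Fn1 had a ratio of 675 (121 to 26696). With each week 5 library alone the ratio was 5750 and 439 for Apoc1 and 1035 and 82.6 for Fn1, in replicates 1 and 2. Fabp5, a fatty acid binding protein, rose by a log2 fold change of 7.17 (SE 0.85), the growth factor Igf1 by 6.62 (SE 0.73) and the integrin Itgax by 6.35 (SE 0.64). Itgax had a UMI in 2 of 901 and 6 of 902 microglia-like cells at week 0. Apoc1, Apoc4 and Apoe are neighbours on the minus strand of chromosome 7 (GRCm38 19689481 to 19692660, 19678083 to 19681479 and 19696109 to 19699188), so reads that run from one gene into the next are uncertain. Spp1 lies on chromosome 5 from 104435118 to 104441050. The summed markers of monocytes in microglia-like cells, relative to total UMIs, were 11.7 and 13.4 CPM at week 0 and 151 and 38.8 CPM at week 5. Fn1, 1 of these markers, was at 143 and 11.4 CPM at week 5, but relative to the effective library size. By counts it had 757 UMIs at week 5, where microglia-like cells held 6084372 and 3013084 UMIs in replicates 1 and 2. It thus made up most of the summed monocyte markers in week 5 replicate 1 and a smaller part in replicate 2. Under limma-voom, Gpnmb (adjusted p = 0.0728), Apoc1 (0.0769) and Fn1 (0.234) did not pass, the highest adjusted p of each over its alternatives.

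**Figure D1:**
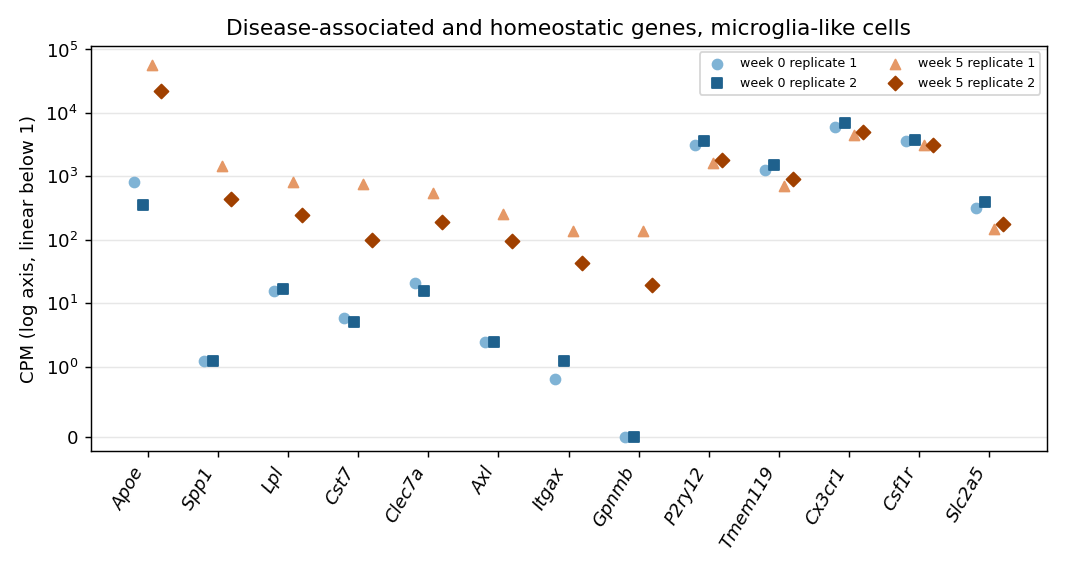
CPM of 8 disease-associated and 5 homeostatic genes in microglia-like cells (log axis, linear below 1), 1 point per library. Week 5 points lie above week 0 points for Apoe to Gpnmb, which had 0 CPM at week 0, and below them for P2ry12 to Slc2a5.

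Of the 25 disease-associated microglia genes, 16 rose and none fell (20 rose when adjusted over the list alone), with a median log2 fold change of 3.48 (camera adjusted p = 3.19e-60; adjusted p = 0.253 with an estimated correlation). Besides those above, Cst7, a cystatin, went from 5.38 ± 0.567 to 426 ± 463 CPM. Clec7a, a receptor for fungal glucans, rose by a log2 fold change of 4.36 (SE 0.47); this annotation types it as a polymorphic pseudogene. The lysosomal membrane gene Cd63 rose by a log2 fold change of 1.83 (SE 0.40). Trem2, the lipid-sensing receptor, had a log2 fold change of 0.27 (SE 0.39, adjusted p = 0.867) and its adaptor Tyrobp 0.88 (SE 0.46, adjusted p = 0.470), and neither passed. Week 5 replicate 1 had the higher value of the week 5 libraries for all 16 genes that rose. Apoe lost its call without week 0 replicate 1 (adjusted p = 0.0505) or replicate 2 (0.210), and Cd63 likewise (0.130 and 0.257) and with thinned cells (0.115). Over all alternatives, the adjusted p of Apoe ran from 1.55e-29 to 0.210 and that of Cd63 from 6.37e-06 to 0.257.

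Among 19 homeostatic microglia genes, only Slc2a5, a fructose transporter, fell (from 354 ± 50.3 to 161 ± 22.4 CPM; log2 fold change -1.14, SE 0.26, adjusted p = 0.0374), and it was also the 1 fall when adjusted over the list alone. The list lay lower as a set, with a median of -0.45 (camera adjusted p = 8.71e-06; adjusted p = 0.317 with an estimated correlation). The purinergic receptor P2ry12 went from 3350 ± 278 to 1692 ± 137 CPM (log2 fold change -0.99, SE 0.39, adjusted p = 0.258) and Tmem119 from 1401 ± 187 to 807 ± 144 CPM (-0.80, SE 0.34, adjusted p = 0.324). Log2 fold changes were -0.43 for the fractalkine receptor Cx3cr1, -0.24 for the growth factor receptor Csf1r and -0.18 for the phagocytic receptor Mertk, with SEs from 0.30 to 0.45, and none passed. The median of the list was -0.68 with the library size as the only scaling. DESeq2's test called P2ry12 (adjusted p = 0.00147) and Tmem119 (0.0494), whose alternatives otherwise ran up to 1. Slc2a5 did not pass without week 0 replicate 1 (adjusted p = 0.0694), week 0 replicate 2 (0.335) or week 5 replicate 2 (0.0741), or with each cell thinned (0.146), in a range from 0.00102 to 0.335.

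The other large falls were in Fam110a (log2 fold change -1.33), the phosphatase Ppm1l (-1.22), the RNA-binding protein Khdrbs3 (-1.20), the adaptor Bank1 (-1.19), Lrba (-1.17) and the kinase activator Cdk5r1 (-1.15), with SEs from 0.21 to 0.26. Lrba went from 223 ± 15.3 to 99.2 ± 22.1 CPM and Bank1 from 85.4 ± 1.32 to 37.7 ± 10.2 CPM. With each cell thinned to 1000 UMIs, adjusted p was 0.0501 for Fam110a, 0.210 for Khdrbs3, 0.0520 for Bank1, 0.299 for Lrba, 0.112 for Cdk5r1 and 0.103 for Camk2n1, so these 6 did not pass. Thinning also leaves far fewer UMIs to test (8415 genes tested and 137 called, against 11061 and 378), so a lost call need not be a lost fall. None of these genes changed direction in any setting. Without week 0 replicate 2, Fam110a (0.164), Lrba (0.121) and Cdk5r1 (0.0869) did not pass either, nor did Fam110a (0.114) and Khdrbs3 (0.0527) without week 5 replicate 2. The lowest adjusted p over the alternatives was between 3.46e-06 for Camk2n1 and 0.000701 for Lrba.

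Interferon response genes rose almost without exception, 24 of 25 over all genes and 25 when adjusted over the list alone, with a median log2 fold change of 3.07 (camera adjusted p = 2.49e-95; adjusted p = 0.229 with an estimated correlation). Ifi204, of a family of DNA sensors, went from 13.4 ± 0.192 to 254 ± 33.6 CPM (log2 fold change 4.24, SE 0.27, adjusted p = 2.10e-05). Oasl2 rose by a log2 fold change of 4.85 (SE 0.34), Usp18, which removes the ubiquitin-like protein ISG15, by 4.36 (SE 0.37) and Rtp4 by 3.40 (SE 0.29). Ifi204 and Oasl2 have close relatives in the genome, among which reads could be split, and their values are uncertain to that extent.

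MHC class I presentation genes rose in 8 of 14 cases (12 when adjusted over the list alone; median 1.54, camera adjusted p = 2.05e-30; adjusted p = 0.188 with an estimated correlation). The classical gene H2-D1 went from 371 ± 31.6 to 1958 ± 339 CPM (log2 fold change 2.40, SE 0.36). The genes H2-Q6, H2-Q7 and H2-Q4 had log2 fold changes of 4.76, 4.43 and 2.12, uncertain because these genes are near copies of one another. H2-D1 did not pass without week 0 replicate 1 (adjusted p = 0.0900) or replicate 2 (0.0949), in a range from 5.65e-19 to 0.0949. MHC class II presentation genes rose in 4 of 7 cases (4 when adjusted over the list alone; median 2.01, camera adjusted p = 3.68e-11; adjusted p = 0.317 with an estimated correlation). The invariant chain gene Cd74 went from 30.2 ± 22.8 to 338 ± 30.9 CPM (log2 fold change 3.43, SE 0.43). Levels of the class II chains went, for H2-Ab1, from 16.2 ± 3.57 to 86.7 ± 34.2, H2-Aa from 9.64 ± 4.28 to 57.1 ± 21.7 and H2-Eb1 from 8.81 ± 4.28 to 37.2 ± 9.28 CPM. Summed markers of border-associated macrophages, which carry much MHC class II RNA, were 387 and 261 CPM in microglia-like cells at week 0 and 261 and 269 CPM at week 5. The sum does not speak for each of its 12 markers. Ms4a7, 1 of them, had 3 UMIs at week 0 against 206 at week 5 (ratio 61.2, counting interval 20.7 to 299, edgeR adjusted p = 0.000510). The median of the list was 1.08 without the Spp1-led cluster and 2.95 at clustering resolution 2, and that of the 4 genes that rose was 1.35 and 3.63 against 2.45. Without the Spp1-led cluster H2-Aa (adjusted p = 0.0512) and H2-Eb1 (0.141) did not pass, the highest values over their alternatives.

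Chemokine genes rose in 11 of 12 cases (12 when adjusted over the list alone; median 4.35, camera adjusted p = 4.20e-35; adjusted p = 0.229 with an estimated correlation). Ccl5 went from 1.04 ± 0.296 to 38.0 ± 14.1 CPM (log2 fold change 5.09, SE 0.44) and Ccl2, which attracts monocytes, from 1.86 ± 0.287 to 81.9 ± 66.5 CPM (log2 fold change 5.50, SE 0.64). Cxcl9, with 2 UMIs at week 0, had a ratio of 129 (counting interval 35.5 to 1073), and Cxcl14 one of 92.7 (31.4 to 452). With week 5 replicates 1 and 2 alone these were 102 and 175 for Cxcl9 and 130.4 and 30.7 for Cxcl14. Complement genes rose in 3 of 10 cases (4 when adjusted over the list alone; median 0.29, camera adjusted p = 8.81e-06; adjusted p = 0.229 with an estimated correlation). These were Itgax, C4b (log2 fold change 4.26, SE 0.47) and C3 (ratio 107, interval 18.8 to 4261, and 145 and 44.8 with week 5 replicates 1 and 2 alone). Genes of NF-kB and inflammatory cytokines rose in 3 of 15 cases (5 when adjusted over the list alone; median 0.21, and -0.05 with the library size as the only scaling; camera adjusted p = 0.00391; adjusted p = 0.317 with an estimated correlation). These were the maturation marker Cd83 (log2 fold change 1.78, SE 0.29), the cytokine Il1b (2.49 ± 1.77 to 21.9 ± 16.3 CPM) and its natural antagonist Il1rn, at least 15.3-fold and at least 17.3-fold higher in week 5 replicates 1 and 2. The median of the complement list was 0.44 without week 0 replicate 1, 0.65 without week 0 replicate 2, 0.76 without week 5 replicate 2, 0.17 with thinned cells and 0.05 with the library size only. That of the cytokine list was 0.38 without week 0 replicate 2, 0.04 without week 5 replicate 1, 0.54 without week 5 replicate 2, 0.14 under the common limit and 0.09 without the Spp1-led cluster. Il1b did not pass without week 5 replicate 1 (adjusted p = 0.0639) or under limma-voom (0.0853, its highest), Il1rn without week 5 replicate 2 (0.0605, its highest), and Cxcl14 under limma-voom (0.0774, its highest).

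Genes of cholesterol storage and efflux rose in 4 of 15 cases (7 when adjusted over the list alone; median 0.65, camera adjusted p = 7.35e-08; adjusted p = 0.317 with an estimated correlation). Besides Apoe and Apoc1, these were Plin2, which coats lipid droplets (20.9 ± 0.364 to 76.3 ± 41.9 CPM; log2 fold change 1.88, SE 0.34), and the cholesterol hydroxylase Ch25h. Ch25h had 2 UMIs at week 0 and a ratio of 218 (59.9 to 1802), or 307 and 69.6 with week 5 replicates 1 and 2 alone. It did not pass under limma-voom (adjusted p = 0.0659, its highest). The list's median was 0.31 without week 5 replicate 1, 0.99 without week 5 replicate 2, 0.41 without the Spp1-led cluster and 0.39 with the library size as the only scaling. Of 17 cholesterol synthesis genes, 0 passed in edgeR, over all genes or adjusted over the list alone, and the list did not differ from other genes (median 0.02, camera adjusted p = 0.883; adjusted p = 0.931 with an estimated correlation), with medians from -0.24 to 0.22 over the alternatives. The isomerase Ebp went from 85.3 ± 27.7 to 86.9 ± 11.3 CPM and the oxidase Msmo1 from 31.8 ± 0.624 to 31.5 ± 5.84 CPM.

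Cd63 was the 1 lysosomal gene of 29 that rose, also when adjusted over the list alone (median 0.53, camera adjusted p = 6.93e-05; adjusted p = 0.512 with an estimated correlation). The list's median was 0.25 without week 5 replicate 1, 0.80 without week 5 replicate 2, 0.29 without the Spp1-led cluster and 0.28 with the library size only. Of 23 phagocytic receptor genes, Axl and the scavenger receptor Colec12 rose, the latter at least 168-fold in week 5 replicate 1 and at least 36.2-fold in replicate 2. Adjusted over the list alone 2 rose and 1 fell, and the list did not pass (median 0.03, camera adjusted p = 0.189; adjusted p = 0.534 with an estimated correlation). Over the alternatives its median ran from -0.18 with the library size as the only scaling to 0.33 without week 5 replicate 2. It was 0.06 and 0.10 without week 0 replicates 1 and 2, -0.08 without week 5 replicate 1 and with thinned cells, 0.21 with no gene filter, 0.24 with DESeq2, -0.02 under the common limit and -0.05 without the Spp1-led cluster. It passed without week 0 replicate 2 (camera adjusted p = 0.0362) and without week 5 replicate 2 (0.00151). Of 11 lytic cell death genes, only Zbp1, a sensor of unusual nucleic acids, rose, also when adjusted over the list alone (2.17 ± 1.02 to 30.6 ± 18.4 CPM; log2 fold change 3.96, SE 0.52). The list itself did not pass (median 0.10, camera adjusted p = 0.380; adjusted p = 0.516 with an estimated correlation). Its median was -0.13 with the library size as the only scaling, -0.04 without week 0 replicate 1, 0.32 without week 0 replicate 2, 0.18 without week 5 replicate 2, 0.23 with thinned cells, -0.08 without the clusters with AY036118 among their leading genes and -0.05 without the Spp1-led cluster.

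**Figure D2:**
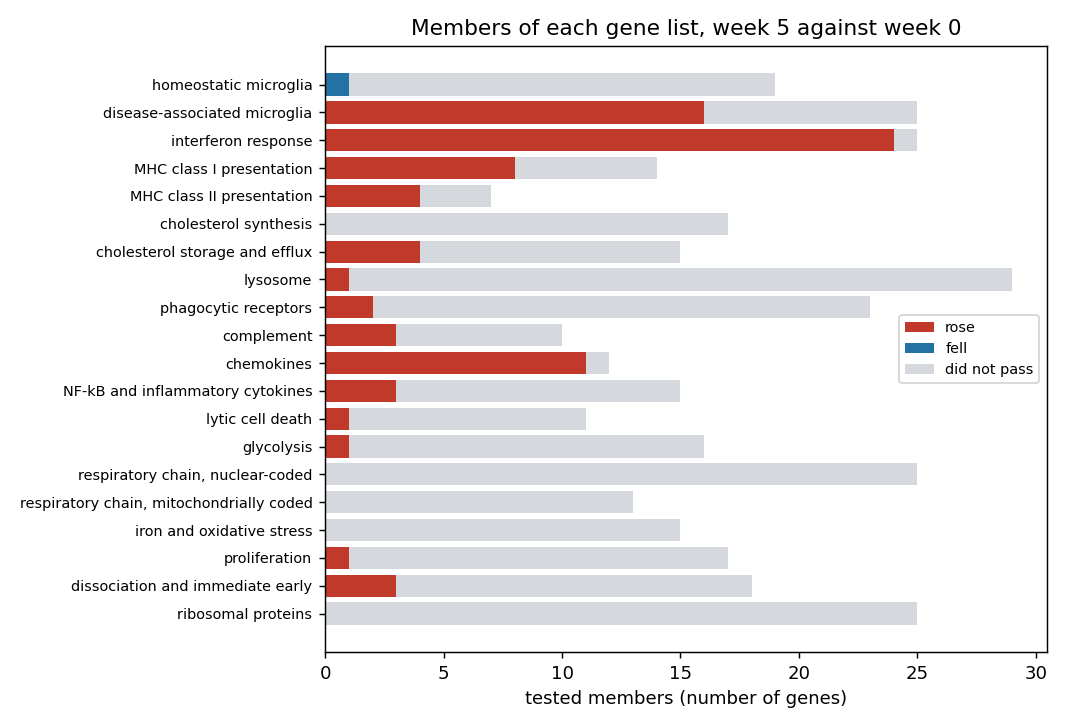
Number of tested members of each of the 20 gene lists that rose, fell or did not pass in microglia-like cells (edgeR adjusted p over all genes tested). Interferon response genes (24 of 25 rose), chemokines (11 of 12) and disease-associated genes (16 of 25) have the highest shares of members that rose.

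Ribosomal protein genes lay higher as a set at week 5, with a median log2 fold change of 1.33 (camera adjusted p = 9.03e-20; adjusted p = 0.317 with an estimated correlation). Over all genes 0 of the 25 passed in edgeR, and all 25 rose when adjusted over the list alone. With all genes tested, 20 rose with a common limit on genes per cell. Rps29 went from 2535 ± 193 to 7629 ± 3655 CPM (adjusted p = 0.130) and Rplp1 from 1836 ± 519 to 3805 ± 1450 CPM (adjusted p = 0.309), both with many pseudogene copies and so uncertain. Both passed under DESeq2's test (3.14e-05 and 0.0210), and Rps29 also without week 5 replicate 2 (0.0420), with no gene filter (0.0246) and the common limit (0.0169), in ranges up to 0.773 and 0.993. The median was 0.82 without week 5 replicate 1 and 0.81 without the Spp1-led cluster. Both shallow clusters with AY036118 among their leading genes (the AY036118 clusters) together made up 74.8%, 15.9%, 22.7% and 42.7% of microglia-like cells in week 0 replicates 1 and 2 and week 5 replicates 1 and 2. The larger, led by Gm43221 with 6 mitochondrially coded genes among its 10 leading genes, had a median of 1280 UMIs per cell and 4.51% mitochondrial UMIs. It alone held 57.3%, 11.6%, 18.5% and 35.3% of the microglia-like cells in the same order. The smaller, led by Mlxipl, had medians of 1075 UMIs and 0.223%. Nuclear-coded respiratory chain genes lay higher (median 0.65, camera adjusted p = 1.02e-05; adjusted p = 0.512 with an estimated correlation), with 0 of 25 passing in edgeR by either adjustment. Under the common limit on genes per cell 2 of them rose. In the main comparison Cox4i1 had a log2 fold change of 1.08 (SE 0.38, adjusted p = 0.184) and Cox8a 1.00 (SE 0.34, adjusted p = 0.167, its lowest over all alternatives being 0.0339). Both passed without week 5 replicate 2 (0.0335 and 0.0436), under DESeq2's test (0.0410 and 0.0359) and with no gene filter (0.0243 and 0.0434), in ranges up to 0.870 and 1. Mitochondrially coded ones had 0 of 13 passing by either adjustment, a median of 0.48 and a camera adjusted p of 0.0421 (adjusted p = 0.630 with an estimated correlation). The level of mt-Co3 went from 3112 ± 1651 to 4669 ± 2064 CPM and mt-Atp6 from 2498 ± 1441 to 3880 ± 2082 CPM. The median of the nuclear-coded list was 0.15 without week 5 replicate 1 (camera adjusted p = 0.259), 1.05 without week 5 replicate 2, 0.36 with thinned cells, 0.38 with the library size as the only scaling and 0.20 without the Spp1-led cluster. That of the mitochondrially coded list turned to -0.07 without week 5 replicate 1 (0.548) and to -0.02 without week 0 replicate 2 (0.373). It was 1.25 without week 0 replicate 1, 1.03 without week 5 replicate 2, 0.83 without the AY036118 clusters, 0.30 with thinned cells, 0.20 with the library size only and 0.23 without the Spp1-led cluster (0.140). Across microglia-like genes, 1499 had an unadjusted p under 0.05.

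Of 16 glycolysis genes, Tpi1 rose (log2 fold change 1.24, SE 0.30, adjusted p = 0.0478), and 9 rose when adjusted over the list alone (median 0.90, camera adjusted p = 2.84e-05; adjusted p = 0.336 with an estimated correlation). The median was 0.29 without week 5 replicate 1 and 0.25 without the Spp1-led cluster. Tpi1 did not pass without week 0 replicate 1 (0.0878), week 0 replicate 2 (0.0573) or week 5 replicate 1 (0.151), or without the Spp1-led (0.228) or AY036118 clusters (0.0569). It also missed with DESeq2 size factors (0.0616), library size only (0.0506), limma-voom (0.0651) and thinned cells (0.179), in a range from 7.60e-05 to 0.228. Of 15 genes of iron and oxidative stress, 0 passed in edgeR over all genes, and adjusted over the list alone 6 rose and 1 fell (median 0.57, camera adjusted p = 0.00801; adjusted p = 0.466 with an estimated correlation). The ferritin subunits Fth1 (1629 ± 315 to 5783 ± 2903 CPM, adjusted p = 0.0730) and Ftl1 (1106 ± 269 to 3061 ± 1525 CPM, adjusted p = 0.123) did not pass. Fth1 passed without either week 5 library (0.0375 and 0.0352), with library size only (0.0292), DESeq2's test, no gene filter (0.00333), no cell filter (0.0340) and the common limit on genes per cell (0.00562), in a range from 2.84e-06 to 0.721. Ftl1 passed without week 5 replicate 2 (0.0478), with DESeq2's test, no gene filter (0.0151) and the common limit (0.0339), in a range from 0.000604 to 0.803. The iron list did not pass without week 0 replicate 1 (camera adjusted p = 0.0598), week 5 replicate 1 (0.116) or the Spp1-led cluster (0.0824), where its median was 0.33, 0.32 and 0.32. It was 0.22 with thinned cells, 0.30 under the common limit and 0.32 with library size only. Under the common limit 3 genes of the iron list rose over all genes tested. Of 17 proliferation genes, the division marker Mki67 rose at least 10.03-fold and at least 14.2-fold in week 5 replicates 1 and 2 and was the 1 rise by either adjustment, also adjusted over the list alone (median 0.85, camera adjusted p = 0.000115; adjusted p = 0.317 with an estimated correlation). Without the Spp1-led cluster the list did not pass (camera adjusted p = 0.0554, median 0.33) and Mki67 had too few UMIs to be tested. The median was 0.48 without week 0 replicate 2, 0.46 under the common limit and 0.52 with thinned cells. Mki67 did not pass without week 5 replicate 2 (adjusted p = 0.0913, its highest).

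Genes of dissociation and immediate early response rose in 3 of 18 cases. Adjusted over the list alone 5 rose and 1 fell (median 0.25, and -0.03 with the library size as the only scaling; camera adjusted p = 0.00318; adjusted p = 0.466 with an estimated correlation). They were the transcription factor Atf3 (14.2 ± 0.977 to 75.1 ± 26.5 CPM) and the chemokines Ccl3 (31.5 ± 22.6 to 371 ± 182 CPM) and Ccl4 (91.1 ± 89.7 to 745 ± 211 CPM), which are also in the chemokine list. Ccl4 did not pass without week 5 replicate 2 (adjusted p = 0.106), without the AY036118 clusters (0.129, its highest) or under DESeq2's test (0.122). The list's median was -0.03 without week 5 replicate 1, 0.55 without week 5 replicate 2, 0.96 without week 0 replicate 1, 0.38 under the common limit and 0.12 with thinned cells. Under the common limit 6 genes of the list rose and 1 fell. With an estimated correlation none of the 20 lists passed, and with the preset one 17 did, 16 upward and 1 downward. The lists share members and are not independent. Apoe, Ch25h, Cd63, Axl and Itgax, named under other lists, are also in the disease-associated list, and Zbp1 is also in the interferon list.

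The share of microglia-like cells with a UMI, at 1000 UMIs per cell, was compared between the libraries. P2ry12 was seen in 89.4% (interval 87.0% to 91.5%) and 94.7% (93.0% to 96.1%) of cells at week 0 and in 59.2% (55.8% to 62.5%) and 62.5% (58.9% to 66.0%) at week 5. Axl was seen in 0.132% and in 0 of 833 cells at week 0, the latter allowing a share of up to 0.360%. At week 5 it was seen in 16.6% (14.1% to 19.2%) and 9.84% (7.81% to 12.2%). Spp1 was seen in 0 of 756 and 0 of 833 cells at week 0, which allows up to 0.397% and 0.360%, and in 15.3% (12.9% to 17.9%) and 7.05% (5.32% to 9.12%) at week 5. Cd74 was seen in 1.85% and 1.68% of cells at week 0 and in 11.1% and 11.8% at week 5. All 13 genes had both groups apart, but the exact permutation p cannot go below 0.333 (n = 2 and 2). Cells of the unnamed clusters led by Ttr or by Pex5l at week 5 gave the background: 9.38% for P2ry12 and for Cst7 (3 of 32 cells each, 1.98% to 25.02%), 6.25% for Spp1 (0.766% to 20.8%) and 87.5% for Apoe. The median cell of these clusters, over both weeks, had 3155 UMIs, against 4864 in microglia-like cells of week 5. Axl and Cd74 were seen in 0 of these 32 cells, which allows up to 9.38%. At 2000 UMIs 1 of 25 such cells had a UMI of Axl and 1 of Cd74, and without thinning 5.71% and 11.4% of 35. The Apoe shares at week 5, 93.5% and 82.2%, were near that background and are not read as expression in so many cells, and the 4.65% of Cst7 in week 5 replicate 2 lay below it. The 7.05% of Spp1 in week 5 replicate 2 was close to its background of 6.25% and within the interval of that background. The background intervals of Spp1 and Cst7 also take in their week 5 replicate 1 shares, and the limit for Axl and Cd74 lies within the intervals of the Axl share in week 5 replicate 2 and of the Cd74 share in replicate 1. So 32 cells do not exclude background for these shares. Without thinning, P2ry12 was seen in 94.3% ± 2.99 of cells at week 0 and 78.0% ± 7.84 at week 5 (SD, n = 2 each).

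**Figure D3:**
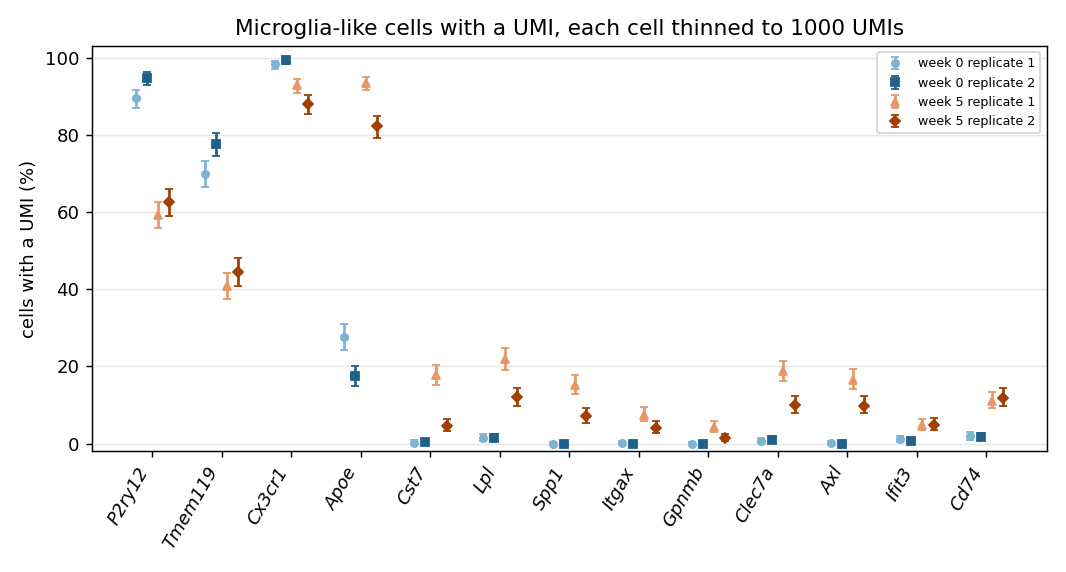
Percent of microglia-like cells with at least 1 UMI of 13 genes after each cell was thinned to 1000 UMIs, 1 point per library with exact 95% binomial intervals. P2ry12, Tmem119 and Cx3cr1 are lower in both week 5 libraries and the other genes higher; background in other cells reached 87.5% for Apoe.

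The clusters held different shares of the microglia-like cells of the 4 libraries. The cluster led by Rtp4 and ribosomal protein genes held 1.89% and 1.66% of them at week 0 and 32.8% and 25.8% at week 5. The one led by Ccl4 and Ccl3 held 0.777% and 0.554% against 9.50% and 10.3%, and the Spp1-led one 0.111% and 0% against 21.7% and 4.69%. The Pnp-led cluster held 16.2% and 48.0% at week 0 and 5.86% and 2.93% at week 5, and the Camk2n1-led one 5.77% and 33.7% against 4.75% and 12.2%. The larger AY036118 cluster was the largest of both week 0 replicate 1 (57.3%) and week 5 replicate 2 (35.3%), and held 11.6% of week 0 replicate 2 and 18.5% of week 5 replicate 1. Because the genes that define these clusters differ between the groups, the sizes describe where the values above come from and are not a result of their own. Without the Spp1-led cluster 337 genes changed, 297 upward and 40 downward, of which 297 were also among the 378.

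Scores of the lists were compared across microglia-like cells within each library. The disease-associated score went with the score of cholesterol storage and efflux at week 5 (Spearman's rank correlation 0.312 and 0.240 in replicates 1 and 2), and less so at week 0 (0.059 and 0.035, and 0.129 and -0.019 at 2000 UMIs per cell). With the lysosome score the correlation was 0.286 and 0.242 at week 0 and 0.216 and 0.364 at week 5, at 2000 UMIs 0.358, 0.134, 0.200 and 0.192, and with the share of UMIs as the score 0.464, 0.288, 0.072 and 0.285. With the interferon score it was 0.043 and 0.020 against 0.148 and 0.137, and with the MHC class II score 0.119 and 0.095 against 0.177 and 0.207 (0.104 and 0.181 against 0.135 and 0.189 at 2000 UMIs). With the homeostatic score it was 0.310 and 0.112 at week 0 and -0.608 and -0.041 at week 5. At 2000 UMIs per cell these 4 values were 0.157, -0.068, -0.762 and -0.505, and with the list's share of UMIs as the score 0.626, 0.379, -0.569 and 0.007, so that the sign held in 1 library of each week. The correlation with cholesterol synthesis ran from -0.028 to 0.065 and with proliferation from -0.022 to 0.098, and over all 3 ways of scoring from -0.053 to 0.078 and from -0.034 to 0.118. The differences between weeks were not tested.

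With all cells summed whatever their class, 285 of 11250 genes changed, 262 upward and 23 downward. Microglia-like cells made up most of this sum, so its values are not independent of those above. Spp1 had a log2 fold change of 9.48 (SE 0.76, edgeR adjusted p = 0.000479), Fabp5 6.97 (SE 0.88), Cst7 6.22 (SE 0.90) and Itgax 5.74 (SE 0.62). The interferon-inducible chemokine Cxcl10 went from 1.48 ± 1.80 to 63.3 ± 76.3 CPM (adjusted p = 0.0442). Among the falls, log2 fold changes were -1.49 for Klhdc8b, -1.41 for Camk2n1, -1.40 for Fam110a and -1.26 for Ppm1l. They were -1.22 for both Bank1 and Lrba, -1.21 for Khdrbs3 and -1.19 for Cdk5r1. With the library size as the only scaling 292 genes rose and 90 fell (76.4% upward against 91.9%), with a median of all genes of -0.24. The count was 151 without week 0 replicate 2, 1373 without week 5 replicate 2 and 107 without the AY036118 clusters, as well as 925 with no gene filter, 499 with a common limit on genes per cell and 139 with thinned cells.

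Macrophage-like cells were too few for a test, with 16, 5, 29 and 25 cells in week 0 replicates 1 and 2 and week 5 replicates 1 and 2 (86071, 29383, 182210 and 105357 UMIs). In them Apoe was high at both times, at 51678 and 29473 CPM at week 0 and 44377 and 49138 CPM at week 5. Cd74 was at 7412 and 11299 CPM at week 0 and at 4094 and 18822 CPM at week 5. Spp1 had 0 UMIs in both week 0 libraries, which allows up to 34.9 and 102 CPM, and 60.4 CPM (exact Poisson interval 30.1 to 108) and 28.5 CPM (5.87 to 83.2) at week 5. Mrc1, the mannose receptor, was at 2974 and 613 CPM at week 0 and at 3128 and 1718 CPM at week 5.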

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

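Tests with crossed replicate numbers, a common limit on genes per cell, only genes listed in every table, and without the AY036118, Spp1-led or Cxcl10-led clusters were chosen after the data were seen; the others were planned. The count of 378 changed genes in microglia-like cells stayed within 1.5 times under 17 alternatives (323 to 478) and became 835 with no gene filter (50 of them not tested otherwise), 580 under the common limit and 137 with thinned cells, where 270 of the 378 were tested and 136 called. In all cells together, 285 became 925, 499 and 139 in the same settings, 107 without the AY036118 clusters, and between 151 (without week 0 replicate 2) and 1373 (without week 5 replicate 2) with a library left out; the causes were not tested. The Spp1-led cluster is in the microglia-like class under 3 of the 5 rankings of its leading genes, 1 of which was kept after all were seen; under the other 2 the class would not have been compared. Without this cluster 337 genes changed, 297 of them shared, 14 lists passed in place of 17, and H2-Aa, H2-Eb1 and Tpi1 lost their calls.

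Of the 54 named genes that changed, 32 kept their call in every setting that tested them and 0 changed direction. With an estimated correlation 0 lists passed and with fry 0, against 14 to 18 with each library left out. As a replicate block, the replicate numbers gave 447 genes in microglia-like cells, 369 in all cells and 18 lists (with the phagocytic receptors, adjusted p = 0.0378), and Slc2a5 lost its call (0.0543). The 2 pairs share only a number, and the correlation of their deviations was -0.190. With the numbers crossed, 793 genes were called in microglia-like cells and 354 in all cells. The mean microglia-like share fell outside the replicate spread with no cell filter (75.2% at week 0 and 84.2% at week 5, against a higher share at week 0 with it), as did the macrophage-like share of week 5 at resolution 0.5 (4.13%). With no cell filter fewer cells were named microglia-like in every library, so the naming differed too. All reversals were in genes that did not pass. The log2 fold change of Msmo1 (-0.0011) was 0.018 with size factors, 0.012 with DESeq2, 0.041 under the common limit, 0.021 with doublets kept, 0.039 with no cell filter, 0.0030 at resolution 2, 0.026 without the AY036118 clusters, 0.00090 without the Spp1-led cluster and -0.20 to 0.22 with a library left out. That of Ebp (0.018) was -0.22 with library size only, -0.063 under the common limit, -0.32 with thinned cells, -0.024 with no cell filter, -0.056 without the AY036118 clusters, -0.059 without the Spp1-led cluster and -0.28 to 0.41 with a library left out. With a library left out, Mertk ran from -0.39 to 0.063 and mt-Atp6 from -0.044 to 1.38; the cause was not tested. With a library left out, the lone sample of its group is assumed to vary like the other group. Depth limits genes with at most 3 UMIs at week 0, which have bounds or wide counting intervals. Of 11061 tested genes, 4679 (42.3%) had both groups apart, against 33.3% by chance. The alternatives of the macrophage-like and class-difference tests were not run, as those tests were not.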

Other observations

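The MHC class II test below, and the choice of the genes in this paragraph, were made after the result was seen. The tests without a cluster and under a common limit on genes per cell were chosen after the data were seen. The SE of a list's median, or of its median ratio, is taken over the genes of the list. These genes move together (estimated correlation 0.97 for ribosomal protein genes and 0.95 for disease-associated genes). Such an SE is too small for the spread between libraries, and a margin of 2 SE is not a test between groups. Of the 378 genes that changed in microglia-like cells, 305 are in none of the 20 lists. Among them, Cybb, the catalytic subunit of the phagocyte oxidase that makes superoxide, went from 4.65 ± 3.35 to 79.5 ± 31.3 CPM (SD, n = 2 each; log2 fold change 4.28, SE 0.44, edgeR adjusted p = 0.000239). The activating Fc receptor Fcgr4 went from 4.87 ± 2.21 to 37.2 ± 4.22 CPM (log2 fold change 2.84, SE 0.32) and Plaur, the receptor of urokinase, from 8.38 ± 1.58 to 48.0 ± 4.31 CPM (2.55, SE 0.27). Fam20c, a kinase of secreted proteins, rose by a log2 fold change of 4.07 (SE 0.34), and the syndecan Sdc3 by 2.98 (SE 0.29). The metalloproteinase gene Mmp12 had 0 UMIs at week 0 and was at least 58.3-fold and at least 21.2-fold higher in week 5 replicates 1 and 2, and Adam33 at least 107-fold and at least 62.1-fold. Rgs7bp, which binds regulators of G-protein signalling, fell (log2 fold change -2.05, SE 0.26, adjusted p = 0.00103), from 32.8 ± 1.43 CPM at week 0.

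Disease-associated genes were higher in week 5 replicate 1 than in replicate 2, with a median log2 ratio of 1.52 (SE 0.19) over the 16 that rose; the 24 interferon genes that rose had 0.58. With both libraries held to the same limit on genes per cell the ratio was 0.89 (SE 0.13), so a lower limit in replicate 2 may account for part of it and not all. That such limits were applied is inferred only from the highest number of genes in a cell (3999 and 2996). Without the shallow AY036118 clusters it was 1.42 (SE 0.18), which argues against their higher share in replicate 2 as the whole cause. Without the Spp1-led cluster, which held 21.7% and 4.69% of the microglia-like cells, it was 0.56 (SE 0.18). A difference between the animals or in the extent of demyelination was not tested and stays open.

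Ribosomal protein genes had a median log2 fold change of 1.33. Without the AY036118 clusters it was 1.15 (SE 0.06) and with each cell thinned to 1000 UMIs 1.10 (SE 0.06). Both lie above 0.5 of the first value by more than 2 SE, but this SE is over genes and not between libraries. In these libraries the shift remained in both settings. This argues against the cells of those clusters, and against a few deep cells, as its whole cause here. It was 0.81 (SE 0.05) without the Spp1-led cluster and 0.82 (SE 0.05) without week 5 replicate 1, so either may hold a part of it. Without week 0 replicate 1, where the larger AY036118 cluster, rich in mitochondrial RNA, held 57.3% of the cells, it was 1.07 (SE 0.07). A higher ribosomal content of microglia-like cells under cuprizone is a hypothesis that these tests leave open, as is any other difference between the libraries, RNA quality included, whose spread left 0 of the 25 genes past the threshold.

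Of 7 MHC class II genes 4 rose in microglia-like cells (camera adjusted p = 3.68e-11; adjusted p = 0.317 with an estimated correlation). The summed level of the list, with members that did not pass or were not tested, was 337 and 488 CPM at week 0 and 841 and 829 at week 5. RNA of macrophages could be the source, since macrophage-like cells carried 10065 to 41981 CPM of these genes. It would also raise macrophage markers, by 46.8 to 522 CPM depending on the library whose macrophage-like cells set the ratio. The sum of these markers changed by -59.1 CPM (SE 63.3), although 1 of them, Ms4a7, rose (3 UMIs at week 0 against 206 at week 5). An earlier form of this test (a log2 ratio of the marker sums of -0.29) and 1 at the pooled ratio of week 5 (a rise of 210 CPM) argued against macrophage RNA. At the ratios of week 5 replicates 1 and 2 alone the rises would be 522 and 80.6 CPM. The change lies below both by more than 2 SE, which argues against macrophage RNA of week 5 as the whole source. But Ms4a7 goes the other way. At the lowest ratio, which rests on 5 cells of week 0 replicate 2, the rise lies within 2 SE of the change. MHC class II transcription in microglia and RNA from macrophages cannot be told apart here.

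A further hypothesis was that a single cluster carried the rise of a list. Without the Cxcl10-led cluster the median log2 fold change of 23 of the 24 interferon genes that rose was 3.72 (SE 0.48; 3.07 for the same 23 with it), while Cxcl10 itself then had too few UMIs to be tested. So that cluster alone is unlikely to carry it. Without the Spp1-led cluster the median of the 16 disease-associated genes that rose was 4.32 (SE 0.61; 6.13 with it). This lies only just more than 2 SE above 0.5 of the value with it, and the SE, taken over genes, is too small. The rise remained in these libraries without that cluster, but the margin itself decides nothing. How large a part it carries is not read from the drop, since disease-associated genes define the cluster.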
